A study of Rattus norvegicus with 13 samples.

How the data were processed

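RNA was sequenced from the peripheral cornea and adjoining limboscleral tissue of male Lewis rats aged 2 months, in a model of limbal stem cell deficiency with corneal neovascularization, per the labels. Each of the 13 libraries was assigned to a treatment and a day by its title: spironolactone at day 3 (n = 3), vehicle at day 3 (n = 3), spironolactone at day 7 (n = 3) and vehicle at day 7 (n = 4). The labels do not state that the libraries came from separate animals, so p-values measure the spread between these libraries. The protocol text gives the same length of treatment for all libraries, so how long the day 7 animals were treated is not settled by the labels.

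The submitters' processing notes name FastQC, fastp, STAR 2.5.3a, RSEM 1.2.28, DESeq2 1.26.0, edgeR 3.28.0, DRAGEN and Picard, and the rat builds rn6 and Rnor_6.0, without the role of each. The day 3 files have the column layout of RSEM gene results and hold the authors' expected counts, which need not be whole, with gene and effective lengths and the authors' TPM values, per the file headers. The day 7 files hold estimated counts, TPM and lengths per Ensembl gene ID, per the file headers; the program that wrote them is not given in the sources used here. Because the layout and annotation differ between days, levels at day 3 were never compared with levels at day 7. The deposited estimated counts were rounded to whole numbers for testing, and the deposited TPM values were used only to check the pairing of genes between days. Totals of estimated counts ran from 18.2 to 25.3 M per library at day 3 and from 17.9 to 26.5 M at day 7. No 2 libraries of a group agreed within sampling noise: over the 15 pairs of libraries within groups, chi-square per gene was 7.63 to 33.6. In the day 3 files 1 row names no gene; it held 0.12% to 0.181% of the counts and was left out of library sizes and tests. Whether the counting used strand is not given in the sources used here, so antisense and overlapping genes may share reads. Members of multigene families such as the keratins, crystallins and class II antigens may also share reads with one another, which is a separate uncertainty.

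Each day had its own fit of spironolactone against vehicle. Genes were kept by edgeR's expression filter with a minimum count of 10, libraries were scaled by TMM, and edgeR 4.0.16 in R 4.3.3 gave quasi-likelihood tests with robust estimation and Benjamini-Hochberg adjustment at 0.05. Standard errors are the log2 fold change divided by the square root of the test's F statistic. Normalised counts are TMM-scaled CPM. Limma 3.58.1 gave the camera test of 32 gene lists on log2 CPM with a prior count of 2 and a preset correlation of 0.01; 31 lists had at least 5 tested members. Of the 608 genes on the lists, 585 were matched in the day 3 files, 5 of them through an older or newer symbol in a RefSeq gene table of the GRCr8 assembly, and 528 were tested. Camera with an estimated correlation and the fry test were run beside it.

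No source used here pairs the day 7 gene IDs with names, so no day 7 gene is named and the gene lists were not tested at day 7. For the comparison of the days alone, genes with a single transcript at day 3 were paired with day 7 genes of the same length where that length occurred once on each side. This gave 1533 pairs, of which 1324 were tested on both days. All 1648 lengths that occurred once at day 3 were found among the constant lengths at day 7, against 53.2% of the same lengths shifted by 1 base. In file order, 98.5% of 1364 paired genes shared the chromosome of their neighbours, against 5.79% after shuffling, and log2 TPM correlated between days with a Pearson r of 0.917 across genes. The pairs were used as a set and never to name a day 7 gene.

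The genes named were chosen by a rule written before the data were examined, as were the tests, the lists and most alternatives. The rule takes genes past the threshold whose groups do not overlap, up to 8 with the largest fold change per direction, or, where fewer than 5 pass, the 5 with the smallest p in that direction with their values. It adds the 4 members with the smallest p of each list past the list test, and 10 fixed genes, of which Pecam1 is not analysed here. A gene named outside this rule is said to have been chosen after its values were seen. Some genes that the rule names are not reported here.

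Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, no filter, a filter of 1 CPM in 3 libraries, effective-length offsets, replicate number as a block, each library left out, and 1 fit over the 13 libraries and the paired genes. DESeq2 gave no adjusted p for 864 genes at day 3 and 4179 at day 7, which were not counted as calls. The tests were checked on counts simulated from the real means and library sizes with 200 changed genes. At day 3, over 14660 genes, edgeR recovered 78% of the genes changed 2-fold and 46% of those changed 1.5-fold, with 12.1% of its calls false; DESeq2 recovered 86% and 66%, with 23.6% false. At day 7, over 15263 genes, edgeR recovered 84% and 64%, with 6.92% false, and DESeq2 88% and 75%, with 17.3% false. For the difference between days, over 1275 genes, edgeR recovered 84% and 34%, with 6.35% false. A list of changed genes planted in the counts simulated for day 3 was found by camera with either correlation and by fry, with 0 unchanged lists called. Those counts were drawn independently for each gene. The check therefore says nothing of false calls among lists whose members move together. The recovered and false shares for single genes also hold for such independent counts, and those of the real libraries may differ. A count of 0 calls is thus no evidence that few genes changed 2-fold.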

Results

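The data were 13 RNA-seq libraries of peripheral cornea and limboscleral tissue from rats with limbal stem cell deficiency, a state in which the cornea loses its epithelial stem cells and vessels grow in. Spironolactone, an antagonist of the mineralocorticoid receptor, was given systemically at 25 mg/kg/day, and the vehicle was 90% olive oil with 10% DMSO. Day 3 had 3 libraries per treatment with 18.2 to 25.3 M estimated counts each, and day 7 had 3 spironolactone and 4 vehicle libraries with 17.9 to 26.5 M. At each day the comparison asked which transcripts differed between spironolactone and vehicle.

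At day 3, transcripts on the corneal epithelial differentiation and wound keratin lists had higher values with spironolactone. Those on the skeletal muscle, blood endothelial and inflammatory lists had lower ones, but no single gene passed the test. These 5 lists passed camera with a preset correlation, but none passed with an estimated correlation (smallest adjusted p = 0.61). Of 14762 genes, edgeR called 0 at an adjusted p of 0.05, with 3332 at an unadjusted p under 0.05 (1798 higher and 1534 lower). The lowest adjusted p was 0.0649. DESeq2 called 1344 genes, 851 higher and 493 lower, and limma-voom called 0. The edgeR count depended on single libraries: it was 781 without vehicle replicate 3, 40 without vehicle replicate 1 and 2 without spironolactone replicate 3. In 32% of genes the 3 spironolactone values lay outside the vehicle range, where chance gives 10% for a single gene. Genes vary together across libraries and the share was not computed for other splits, so this difference is not a test.

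The 5 higher genes with the smallest p were Acap1, Msln, Cdh3, Col17a1 and Hadh. Cdh3 encodes P-cadherin of basal epithelium and had 206 ± 9.16 CPM (SD, n = 3) with spironolactone and 150 ± 3.08 CPM (SD, n = 3) with vehicle. Col17a1, a hemidesmosomal collagen, had a log2 fold change of 0.83 (SE 0.095), Acap1 0.59, Msln 0.47 and Hadh 0.48. The 5 lower genes were Myog, Myom2, Csrp3, Pde2a and Wfdc1. Myog, a transcription factor of muscle differentiation, had 0.581 ± 0.051 CPM with spironolactone and 3.45 ± 0.676 CPM with vehicle, a log2 fold change of -2.57 (SE 0.24). The muscle genes Myom2 and Csrp3 had log2 fold changes of -1.62 and -2.33, Pde2a -0.92 and Wfdc1 -0.75. Each of these 10 genes had an adjusted p of 0.0649, above the threshold.

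Of 31 gene lists tested at day 3, 17 passed camera with a preset correlation, 6 higher and 11 lower with spironolactone. None passed with an estimated correlation, where the smallest adjusted p = 0.61. None passed fry's test of change in 1 direction, where the smallest was 0.123. Estimated correlations reached 0.952 for skeletal muscle, 0.899 for cell division and 0.813 for blood endothelium, and the lowest was -0.0903 for adipocyte markers. Where members move together so closely, p-values from the preset 0.01 can be far too small. With estimated correlations, camera's unadjusted p among the 17 lists ran from 0.0609 for corneal epithelial differentiation to 0.487 for cell division. Camera on ranks called 16, without hypoxia and glycolysis (adjusted p = 0.0632). Fry's test of change in either direction also called 16 of the 31 lists, but not the same ones. Among others, it called the limbal and nerve lists (adjusted p = 0.0102 each), which did not pass camera. It did not call blood endothelium and angiogenic signalling (adjusted p = 0.0687 each) or cell division (adjusted p = 0.37), among others. No list had a member past the threshold when adjusted over all genes tested. In each of the fits with 1 library left out, 7 lists passed: angiogenic signalling, blood endothelium, collagens and fibrosis, corneal epithelial differentiation, wound keratins, cholesterol synthesis and skeletal muscle. The other 10 each lost the call in at least 1 of these fits, with a highest adjusted p between 0.052 for neutrophil markers and 0.31 for hypoxia and glycolysis. Without spironolactone replicates 1, 2 and 3 in turn, 17, 11 and 13 lists passed, and without vehicle replicates 1, 2 and 3 it was 14, 13 and 18.

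In 6 of the 17 lists the spironolactone medians per library lay outside the range of the vehicle libraries: wound keratins, corneal epithelial differentiation, cholesterol synthesis, collagens and fibrosis, skeletal muscle, and retina, lens and melanocyte markers. In the other 11 they overlapped. The share of mitochondrial transcripts, compared after the data were seen, was lower in every spironolactone library than in any vehicle library, at 4.53% ± 0.342 (SD, n = 3) against 5.36% ± 0.200 (SD, n = 3) with vehicle. The libraries ranged from 4.17% to 4.85% and from 5.13% to 5.48%, and an exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow.

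**Figure D1:**
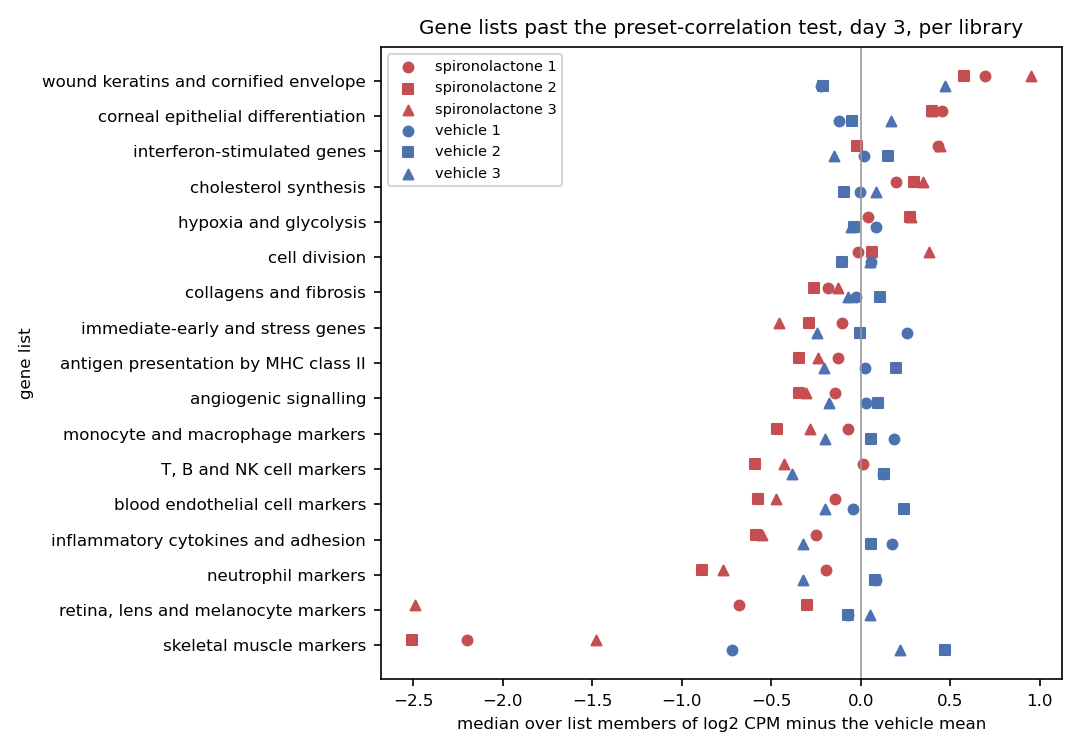
Median over the members of each gene list of log2 CPM minus the vehicle mean (x axis), for the 17 lists past the preset-correlation test at day 3; each point is 1 library, coloured by treatment and shaped by replicate. The 3 spironolactone libraries lie at -2.20, -2.51 and -1.48 for skeletal muscle, and vehicle replicate 3 lies at 0.47 for wound keratins, beside 0.57 in spironolactone replicate 2.

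Of the epithelial lists, corneal epithelial differentiation and wound keratins were higher with spironolactone by camera, while limbal markers (adjusted p = 0.266) and conjunctival and goblet cell markers (adjusted p = 0.154) did not pass. In the corneal epithelial differentiation list 16 of 18 tested members had positive log2 fold changes, with a median of 0.38 (adjusted p = 1.7e-06 with the preset correlation, adjusted p = 0.61 with an estimated correlation), and 12 were higher when adjusted over the list alone. Cdh1, the E-cadherin of epithelial junctions, had 427 ± 19.9 CPM with spironolactone and 298 ± 34.9 CPM with vehicle (n = 3 each). The log2 fold change was 0.74 (SE 0.15) for the desmosomal gene Dsp, 0.46 for the tight junction gene Cldn4 and 0.35 for the transcription factor Klf4. In the list of wound keratins and cornified envelope 15 of 15 members were positive, with a median of 0.88 (adjusted p = 1.6e-06, adjusted p = 0.61 with an estimated correlation), and 8 were higher when adjusted over the list alone. Krt17, a keratin of wounded epithelium, had 1248 ± 129 CPM against 773 ± 113 CPM, with log2 fold changes of 0.61 for Dsc2, 0.88 for Cnfn and 1.09 for Krt1. The corneal keratin gene Krt12 had a log2 fold change of 0.30 (SE 0.17) and the limbal keratin gene Krt15 0.58 (SE 0.14), with adjusted p of 0.333 and 0.0892. Krt12 was low, at 11.6 CPM with spironolactone and 9.41 CPM with vehicle, where Krt15 had 2644 and 1768 CPM. The corneal epithelial differentiation list thus passed the preset-correlation test without a detectable difference in Krt12. Skeletal muscle markers, with a median of -2.08, and the mitochondrial share were lower in the same 3 libraries.

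Among metabolic and proliferation lists, cholesterol synthesis had 19 of 20 members positive, with a median log2 fold change of 0.27 (adjusted p = 1.8e-06, adjusted p = 0.61 with an estimated correlation), and 15 were higher when adjusted over the list alone. Fdft1, a squalene synthase gene, had 146 ± 10.3 CPM with spironolactone and 115 ± 8.92 CPM with vehicle (n = 3 each), and the log2 fold changes of Sc5d and Srebf2 were 0.27 and 0.22. The list of hypoxia and glycolysis had 13 of 18 members positive, with a median of 0.23 (adjusted p = 0.0433, adjusted p = 0.61 with an estimated correlation). Its members went both ways, with Egln3 at 0.58 and Hk2 at -0.49; when adjusted over the list alone 5 were higher and 1 lower. The cell division list had 26 of 27 members positive with a median of 0.15 (adjusted p = 0.00298, adjusted p = 0.61 with an estimated correlation), 0 when adjusted over the list alone, and Plk1 at 0.28 (SE 0.13). Its median per library was 0.38 in spironolactone replicate 3, -0.01 and 0.06 in the other spironolactone libraries and between -0.10 and 0.06 with vehicle. Without the replicates 3 of both treatments, left out after the data were seen, the median log2 fold change was 0.07. Interferon-stimulated genes were positive in 22 of 24 members, with a median of 0.34 (adjusted p = 0.00357, adjusted p = 0.61 with an estimated correlation). Oasl had a log2 fold change of 0.78 and was the 1 member higher when adjusted over the list alone. Spironolactone replicate 2, at -0.02, lay within the vehicle range of -0.15 to 0.15, and the median was 0.18 without the replicates 3. Beside these lists, skeletal muscle markers (median -2.08) and the mitochondrial share (4.53% against 5.36%) were lower in the 3 spironolactone libraries.

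Blood endothelium, angiogenic signalling, and collagens and fibrosis were lower with spironolactone by camera, while lymphatic endothelium (adjusted p = 0.241) and matrix proteases (adjusted p = 0.526) did not pass. Blood endothelial markers were negative in 17 of 18 members, with a median log2 fold change of -0.42 (adjusted p = 7.1e-05, adjusted p = 0.61 with an estimated correlation), and 5 were lower when adjusted over the list alone. Plvap, a gene of fenestrated endothelium, had 56.9 ± 4.01 CPM with spironolactone and 80.6 ± 11.3 CPM with vehicle, and the endothelial transcription factor gene Erg had 16.8 ± 0.864 against 23.8 ± 2.39 CPM. Icam2 and Emcn had log2 fold changes of -0.53 and -0.41. In the angiogenic signalling list 25 of 30 members were negative, with a median of -0.26 (adjusted p = 0.00214, adjusted p = 0.61 with an estimated correlation) and 0 when adjusted over the list alone. The ligand gene Apln had a log2 fold change of -0.75 and the receptor gene S1pr1 -0.68, while Jag1 and Notch1 of the Notch pathway had 0.41 and 0.32. Vegfa had a log2 fold change of -0.26 (SE 0.11) and its receptor gene Kdr -0.70 (SE 0.32), with adjusted p of 0.234 and 0.262. Collagens and fibrosis genes were negative in 20 of 24 members, with a median of -0.19 (adjusted p = 6.1e-04, adjusted p = 0.61 with an estimated correlation), and 1 was lower when adjusted over the list alone. Lox, which encodes a collagen cross-linking enzyme, had 410 ± 22.3 CPM against 525 ± 65.1 CPM (n = 3 each), and Tgfb2 and Col6a3 had log2 fold changes of -0.27 and -0.26. In the same libraries skeletal muscle markers had a median of -2.08 and mitochondrial transcripts took 4.53% against 5.36%. For blood endothelium spironolactone replicate 1, at -0.14, lay above vehicle replicate 3, at -0.20, and for angiogenic signalling at -0.14 against -0.18.

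The lists of inflammatory molecules, neutrophils, macrophages, class II antigen presentation and lymphocytes were also lower by camera, while mast cells (adjusted p = 0.266) and complement (adjusted p = 0.365) did not pass. Inflammatory cytokines, chemokines and adhesion molecules were negative in 22 of 30 members, with a median of -0.56 (adjusted p = 0.00742, adjusted p = 0.61 with an estimated correlation) and 3 lower when adjusted over the list alone. The endothelial selectin gene Sele had 4.45 ± 1.33 CPM with spironolactone and 10.6 ± 1.6 CPM with vehicle, and Selp 9.18 ± 2.33 against 23.8 ± 8.69 CPM. Nlrp3, an inflammasome gene, had a log2 fold change of -0.53 and Il1rn, which encodes an interleukin-1 receptor antagonist, had 0.57. Neutrophil markers were negative in 8 of 9 members (median -0.62, adjusted p = 0.00907, adjusted p = 0.61 with an estimated correlation), with Csf3r at -0.72, S100a9 at -0.83 and Mmp8 at -1.60, and 4 were lower when adjusted over the list alone. Monocyte and macrophage markers were negative in 18 of 20 members (median -0.27, adjusted p = 0.00311, adjusted p = 0.61 with an estimated correlation), with Adgre1 at -0.30 and 1 lower when adjusted over the list alone. Class II antigen presentation genes were negative in 10 of 10 (median -0.25, adjusted p = 0.00907, adjusted p = 0.61 with an estimated correlation), with Cd74 at -0.23. T, B and NK cell markers were negative in 9 of 9 (median -0.37, adjusted p = 0.0433, adjusted p = 0.61 with an estimated correlation), with Cd2 at -0.80. Neither list had a member lower when adjusted over the list alone. Immediate-early and stress genes were negative in 13 of 16 (median -0.25, adjusted p = 0.0237, adjusted p = 0.61 with an estimated correlation), with Atf3 at -0.66 and Hspa1b at 0.45; when adjusted over the list alone 1 was higher and 2 lower. In each of the 6 lower lists of this group the median of spironolactone replicate 1 lay above that of vehicle replicate 3, as at -0.25 and -0.32 for inflammatory molecules. The muscle gene Acta1, at -1.98, and the mitochondrial share were also lower in the same 3 libraries.

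Markers of tissues next to the cornea also differed between libraries. All 14 tested skeletal muscle markers were lower when adjusted over the list alone, with a median log2 fold change of -2.08 (adjusted p = 3.8e-10, adjusted p = 0.61 with an estimated correlation). Acta1, the skeletal actin gene, had 52.1 ± 16.2 CPM with spironolactone and 205 ± 70.9 CPM with vehicle, and Mylpf, Tnnc2 and Actn3 had log2 fold changes of -2.29, -2.18 and -1.73. The list of retina, lens and melanocyte markers was negative in 14 of 17 members (median -0.98, adjusted p = 0.0304, adjusted p = 0.61 with an estimated correlation), with 0 when adjusted over the list alone. Its median per library was -2.49 in spironolactone replicate 3 and -0.68 and -0.30 in the others, and the median log2 fold change was -0.55 without the replicates 3. Its rod gene Gnat1, given because that library stood apart, was at 51.5 CPM in spironolactone replicate 3 and between 875 and 1558 CPM in the other 5 libraries. The lens gene Cryaa was at 230 CPM in vehicle replicate 3 and between 0.886 and 22 CPM elsewhere. Without spironolactone replicate 3 and vehicle replicate 3, a choice made after seeing the data, edgeR called 1040 genes and camera 15 lists, 14 of them among the 17; the lists of interferon-stimulated, cell division and hypoxia genes no longer passed.

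**Figure D2:**
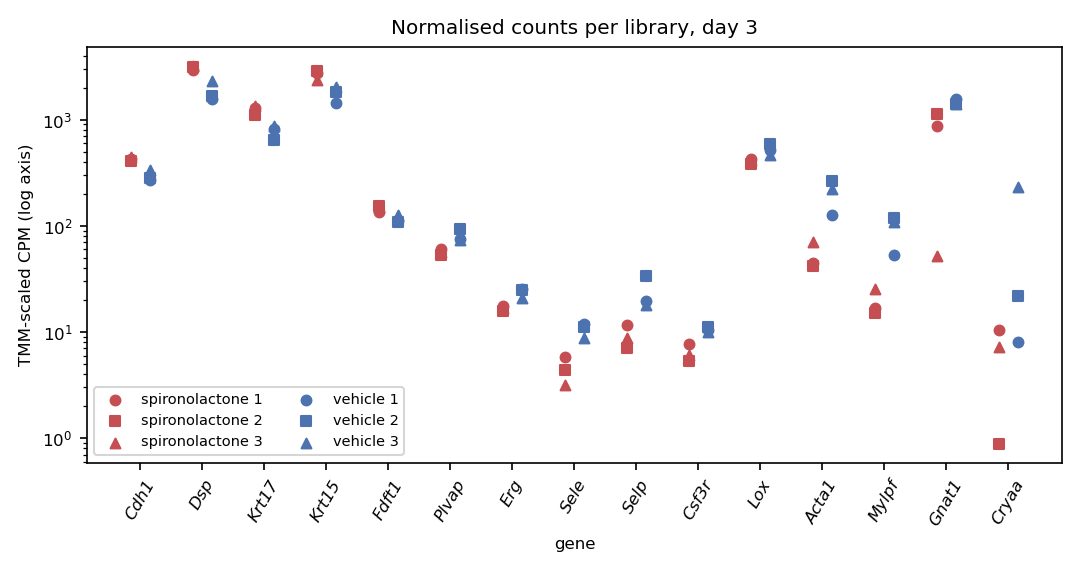
TMM-scaled CPM (y axis, log scale) of 15 genes in the 6 libraries of day 3; each point is 1 library, coloured by treatment and shaped by replicate. Acta1 and Mylpf are lower in all 3 spironolactone libraries, Gnat1 is low in spironolactone replicate 3 at 51.5 CPM, and Cryaa is high in vehicle replicate 3 at 230 CPM.

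The receptor that spironolactone blocks showed no detectable difference in transcript level. Nr3c2, the mineralocorticoid receptor gene, had 11.8 ± 1.81 CPM with spironolactone and 12.5 ± 0.806 CPM with vehicle at day 3 (adjusted p = 0.722), and Nr3c1, the glucocorticoid receptor gene, had a log2 fold change of -0.14 (adjusted p = 0.351). Sgk1, a kinase gene induced by both receptors, had 147 ± 18.6 against 188 ± 22.7 CPM, a log2 fold change of -0.36 (SE 0.12, adjusted p = 0.156). Fkbp5 and Tsc22d3, known glucocorticoid targets, had log2 fold changes of 0.07 (SE 0.22) and -0.11 (SE 0.082). The sign depended on single libraries: the log2 fold change of Nr3c2 at day 3 was 0.0388 without spironolactone replicate 3, and the log2 fold change of Fkbp5 at day 3 was -0.119 without spironolactone replicate 1. The list of both receptors and their targets was negative in 19 of 25 members with a median of -0.14 and did not pass camera (adjusted p = 0.0657).

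At day 7, edgeR called 0 of 15396 genes, with 2018 at an unadjusted p under 0.05 and a lowest adjusted p of 0.328. DESeq2 called 88, 58 higher and 30 lower, and limma-voom called 0. The groups did not overlap in 12.3% of genes, where chance gives 5.71% for a single gene, which again is not a test. The genes at this day carry IDs that no source used here pairs with names. The 2 higher IDs with the smallest p were ENSRNOG00000007582, with 31.2 ± 1.29 CPM (SD, n = 3) against 22.8 ± 1.7 CPM (SD, n = 4), and ENSRNOG00000026919, with a log2 fold change of 0.66 (SE 0.11). The 2 lower IDs were ENSRNOG00000004635, with 239 ± 38.4 against 401 ± 47 CPM, and ENSRNOG00000046867, with a log2 fold change of -0.57 (SE 0.10). All 4 had an adjusted p of 0.328. Without spironolactone replicate 2, spironolactone replicate 3 or vehicle replicate 4, edgeR called 1 gene each.

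To ask whether the effect of spironolactone differed between days, the 1324 genes paired by length were tested. edgeR called 0 genes for a difference between the effects at day 7 and day 3, with 161 at an unadjusted p under 0.05; DESeq2 called 3 and limma-voom 0. Without vehicle replicate 3 of day 3 edgeR called 6. Across these genes, which are not independent replicates, the fold changes of the days correlated with a Pearson r of 0.53 and a Spearman rho of 0.388, and 62.3% had the same sign. Without an expression filter r was 0.303. The comparisons of the days share no libraries. Over the 1302 genes with a day 3 log2 fold change between -1 and 1, a limit chosen after seeing the data, r was 0.33 and rho 0.368. All 22 genes beyond that limit had lower values at day 3, and 19 of them were also negative at day 7. The median of the 22 at day 7 was -0.96. By their day 3 names, looked up after the values were seen, the lowest included muscle genes. Among them were the myosin genes Myh8, Myh3 and Myh15, with day 3 log2 fold changes of -2.94, -2.44 and -2.43. Not all were muscle genes, as Adamts4 had -2.28. The correlation thus rests in part on muscle genes.

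**Figure D3:**
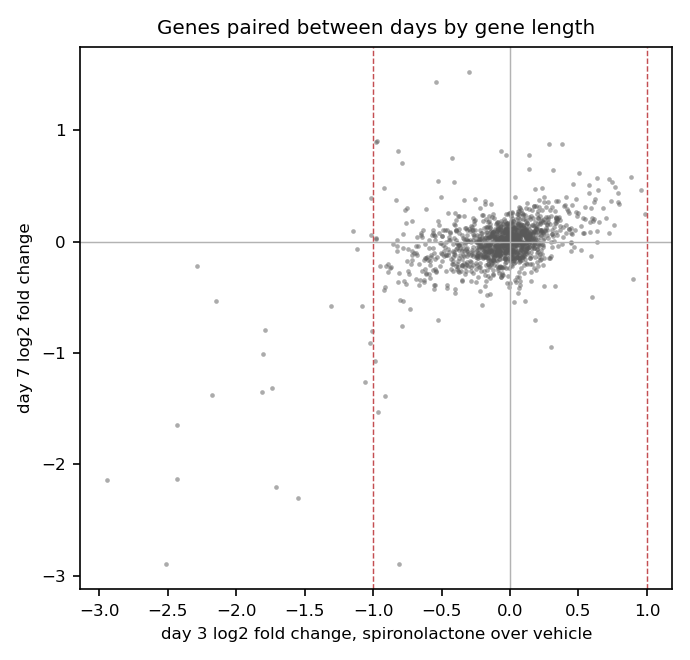
Log2 fold change of spironolactone over vehicle at day 3 (x axis) and day 7 (y axis); each point is 1 of 1324 genes paired between days by length, and dashed lines mark -1 and 1. The 22 genes left of -1 are mostly negative at day 7, and r is 0.53 over all points.

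Of the paired genes that DESeq2 called at day 3, 80 were higher and 70 lower. Among the 80, 78 had positive log2 fold changes at day 7, with a median of 0.20. Among the 70, 17 were positive, with a median of -0.12. Of the other 1174 genes 47.5% were positive. DESeq2 called 2 paired genes higher on both days, where independent lists would share 0.544, and 0 lower on both.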

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

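The permutation test here was chosen after its result was seen. The row of the day 3 files that names no gene, which no comparison used, held a mean of 0.169% of the estimated counts with spironolactone (SD 0.0116, n = 3) and 0.13% with vehicle (SD 0.0127, n = 3). Every spironolactone library lay above every vehicle library. An exact two-sided permutation test of the means gave p = 0.1, the smallest that 3 against 3 libraries allow. What this row counts is not given in the sources used here.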

How the results depend on the processing

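Of these alternatives, the 0.10 threshold, the fit without robust estimation, the limit on day 3 fold changes and leaving out a pair of libraries were chosen after seeing the data. The count of genes called at day 3, 0 with edgeR, became 1344 with DESeq2, 148 without a filter, 79 in 1 fit of the 13 libraries over the paired genes, 1043 at an adjusted p under 0.10 and 1040 without the pair of libraries with unlike photoreceptor or lens transcripts; leaving out each library gave 0 to 781, the highest without vehicle replicate 3. DESeq2 shared 946 genes with the 1043, and 649 with the 781. The count of genes called at day 7 was 88 with DESeq2 and 0 to 1 with each library left out. The treatment-by-day count was 3 with DESeq2 and 0 to 6 with each library left out. Replicate numbers showed no clear pairing of the libraries. By title number, same-numbered libraries correlated in their deviations from the group means at 0.0898, -0.0845 and 0.0486 at day 3. At day 7 it was 0.00589, 0.0631 and 0.202. So few correlations cannot exclude a pairing. A block by title number gave 861 genes at day 7, 0 at day 3 and 17 lists. By description number it gave 545 genes at day 3, 1 at day 7 and 2 for the treatment-by-day difference. At day 3 the replicates 3 of both treatments share no description number with another library. Each stood alone in its block and added nothing to the estimated effect, so that fit resembles the one without the pair. At day 7 vehicle replicate 4 stood alone by title number and vehicle replicate 1 by description number. The correlation of the days, 0.53, was 0.472 with limma-voom, 0.303 without a filter, 0.42 and 0.444 with the blocks by title and description number, 0.333 over genes with day 3 changes between -1 and 1, and 0.432 to 0.59 with each library left out. The 17 lists at day 3 became 0 with an estimated correlation and 0 with fry, and 11 to 18 with each library left out. The other alternatives left these values the same or within 1.5 times. Among 87 named day 3 genes 2 changed sign, neither past the threshold. The log2 fold change of Nr3c2 at day 3 was 0.0347 with the description block, 0.0388 without spironolactone replicate 3 and 0.0391 without the pair, and -0.154 to 0.0388 with each library left out. The log2 fold change of Fkbp5 at day 3 was -7.5e-04 with limma-voom, -0.0266 with the description block and -0.119 without spironolactone replicate 1, and -0.119 to 0.296 with each library left out. Over all alternatives, 180 values of the 87 genes passed the threshold that the main edgeR fit missed, 58 of them with DESeq2. The reverse could not occur, since no gene passed in the main fit. For the 17 lists, all past the threshold in the main test, 63 values missed it. The causes were not tested. List tests at day 7 were not run.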

Other observations

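Tests of the muscle, endothelial and inflammatory lists against the keratocyte, nerve and ciliary body lists, of fibre genes outside the muscle list, over genes with small day 3 changes, and of genes positive at day 7 were chosen after the results were seen. Several lists that did not pass as a whole held members that went both ways at day 3. Among limbal stem and progenitor markers, 11 of 20 were positive; when adjusted over the list alone 7 were higher and 6 lower. Tp63, a transcription factor gene of basal epithelium, had 126 ± 5.67 CPM with spironolactone and 79.3 ± 10.2 CPM with vehicle, and Itgb4 and Krt14 had log2 fold changes of 0.51 and 0.79, while Cebpd and Cxcl14 had -1.31 and -0.74. Among oxidative stress genes 6 were higher and 3 lower when adjusted over the list alone, with Gpx2 at 0.60 and Gpx3 at -0.32. Among the receptor targets Zbtb16 had 1.06 (SE 0.39) and the epithelial sodium channel gene Scnn1g -1.32 (SE 0.45). These genes were chosen after their values were seen, and none passed when adjusted over all genes tested.

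Lists near 0 were keratocyte and corneal stroma (median log2 fold change -0.06, 14 members), nerve and Schwann cell (0.04, 20 members) and ciliary body, iris and trabecular meshwork (median -0.0040, 15 members). Oxidative stress (-0.03, 20 members) and matrix proteases (-0.04, 21 members) lay near 0 as well. Other lists that did not pass had medians of -0.17 for lymphatic endothelium, -0.10 for anti-angiogenic factors, -0.11 for complement and 0.24 for conjunctival and goblet cells. The medians were -0.18 for nerve growth factors, -0.50 for mast cells and -0.23 for adipocytes. The erythrocyte list, with 4 genes past the expression filter and a median of -0.16, was too short for the list test. At day 7, only 2 lists had at least 5 members paired by length: angiogenic signalling with 9 members (median -0.01) and matrix proteases with 5 (median -0.20).

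Chance was weighed by regrouping the libraries. At day 3 the 6 libraries allow 10 splits, too few for a share under 0.05. All 10 gave at least the 0 genes of the real one, and the highest other gave 5. Any split reaches a count of 0, so such a count weighs nothing for or against chance, here and below. The real split had 3332 genes at an unadjusted p under 0.05, as many as 1 of 10, and the highest other had 1463. For lists, 2 of 10 splits gave as many: the real one called 17 and the highest other called 18, with spironolactone replicate 1 beside vehicle replicates 1 and 2. At day 7, 35 of 35 splits gave at least the 0 genes of the real one (highest other 3). Chance was not excluded for the 2018 genes at an unadjusted p under 0.05, since 4 of 35 splits gave as many. The highest other gave 3523, with vehicle replicates 1, 2 and 3 apart from the rest. For the treatment-by-day difference 100 of 100 drawn splits gave at least the 0 of the real one, and the highest other called 228, with the treatments kept at day 3 and vehicle replicates 1, 2 and 3 again apart from the rest at day 7. The next highest called 17, and whether a structure of the day 7 libraries lies behind the 228 was not tested.

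The correlation between days was weighed against chance and against carried-over tissue. In 19 of 350 pairs of splits the size of r was at least 0.53, with a highest other of 0.666, so chance was not excluded, and r was 0.303 without an expression filter. Of the 80 genes DESeq2 called higher at day 3, 78 were positive at day 7, as in 2 of 35 splits (highest other 78), so chance was not excluded here either. Genes of muscle and retina with large fold changes could carry the correlation. Over genes with day 3 log2 fold changes between -1 and 1, whichever tissue they mark, r was 0.333 where all genes gave 0.53. Over the same genes rho was 0.368 where all genes gave 0.388. The lower r means that part of it rests on the 22 genes beyond that limit. That rho changed little and r stayed positive without them argues against those genes as the whole cause. An r of at least 0.333 in size was reached in 11 of 350 pairs of splits (highest other 0.455), a share under 0.05. Each split applied the limit to its own day 3 fold changes, so the genes differed between splits. The share therefore says nothing of carried-over tissue. Genes of these tissues with smaller changes stay open.

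For the muscle, vessel and inflammatory values at day 3, a candidate explanation is a larger epithelial share that dilutes every other cell type alike. Against the keratocyte median of the same library, the muscle median was at most -1.44 in the spironolactone libraries and at least -0.642 in the vehicle libraries, which argues against dilution for muscle. Dilution would also lower the keratocyte, nerve and ciliary body lists by about the endothelial median of -0.42 or the inflammatory median of -0.56, but these lay at -0.06 (SD over members 0.25), 0.04 (SD 0.40) and -0.0040 (SD 0.35). The smallest shortfalls, 0.358 and 0.498 for the keratocyte list, exceeded its SD, as did the others theirs. The medians of these 3 lists thus did not fall with either change. The 3 lists were picked after their values were seen, so they cannot decide on dilution. It stays open for both changes: lymphatic, adipocyte and mast cell lists, at -0.17, -0.23 and -0.50, were not short by more than their spread. Against the keratocyte median of the same library, the highest spironolactone values (0.023 for endothelium, -0.0853 for inflammation) also lay above the lowest vehicle values (-0.24 and -0.362). Less muscle carried into the tissue piece stays open: of 3 fibre genes outside the list, 2 had a log2 fold change under -1 (Tnni1 and Tnnt1) and Myh7 had -0.81, too few to decide, and an effect of the treatment on these cells is open as well.

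The low photoreceptor transcripts of spironolactone replicate 3 may come from less retina carried into that tissue piece. In a second set of rod genes 11 of 11 had a log2 ratio under -1 against the mean of the other 5 libraries (median -3.85), which argues against a difference in a few genes. Bipolar cell genes, from another layer of the retina, had a median ratio of -3.63 and 9 of 10 under -1, as less retina would give, with Trpm1 at -0.23. Of 4 amacrine or ganglion cell genes only 2 were under -1 (Gad1 at -4.58 and Slc17a6 at -3.51), while Slc6a9 had -0.66 and Rbpms 0.20, and the pigment cell genes Dct and Tyrp1 had 0.16 and 0.07. No biological explanation was tested, and loss of retinal cells in that sample stays open.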
